A study of Homo sapiens with 12 samples.

How the data were processed

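RNA levels were measured by sequencing of total RNA libraries from TE-1 cells, a human oesophageal cancer line. The 12 libraries formed 4 groups of 3, named here OE_IFI6 (vector that overexpresses IFI6), OE_control (its control vector), sh_IFI6 (short hairpin against IFI6) and sh_control (its control hairpin). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

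The deposited values are FPKM (fragments normalized to transcript length and to the mapped fragments of the library), computed by the authors for genes and for transcripts. The tools HISAT2, StringTie, Cuffdiff and edgeR are named per the submitters' processing notes, with no versions or roles. The genome build, the annotation release and whether counting used strand are not given in the sources used here. Gene coordinates in the deposited tables overlapped those of GENCODE release 29 (GRCh38) for all 19702 of 19771 protein-coding genes whose identifiers matched, and 52.7% had the same bounds. For transcripts, 205999 of 259360 identifiers matched and 93.3% of these had the same bounds. Coordinates are given as the deposited tables give them. Because strand use is not given, it is unknown whether reads of overlapping and antisense genes were separated. Near-identical copies such as HSPA1A and HSPA1B are reported as uncertain because the split of reads between them is not known. A gene's value is the sum of its transcripts' values in the deposited tables.

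No read counts per library were used here. Low values of single-transcript genes lay on steps, as values made from reads do. The steps numbered 29.8 to 38.4 per kilobase at 1 FPKM, a ratio of 1.29 between the highest and the lowest library. If a step is 1 fragment, a transcript of 1 kb at 1 FPKM rests on that many fragments. Only 23.3% to 27.3% of low values over 31255 single-transcript genes lay within 1% of a whole step, so whole reads were not recovered and no count test was run. Values near 1 FPKM therefore carry the largest counting error.

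Protein-coding genes with a mean of at least 1 FPKM over the 12 libraries were tested (10925 genes), as log2(FPKM + 1). A fold change on this scale understates the change of genes near 1 FPKM. Limma 3.58.1 (R 4.3.3; tables read with data.table, version 1.17.8) fitted 1 group-means model to the 12 libraries, which left 8 residual degrees of freedom, with a trended prior variance. Contrasts were OE_IFI6 against OE_control, sh_IFI6 against sh_control, the difference between those effects, and OE_control against sh_control. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for "rose" and "fell". Transcripts in the deposited lncRNA table with a mean of at least 1 FPKM were tested the same way (6496 transcripts). IFI6 was also compared by exact permutation of 3 against 3 libraries, which cannot give a p under 0.1.

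For gene groups, 32 lists were fixed before the data were examined, as were the main tests, the alternatives and the rule for named genes. Limma's camera with a preset correlation of 0.01 between genes tested the 30 lists with at least 5 tested members, adjusted over the lists. It was repeated with an estimated correlation, and fry was run as an alternative. For members of a list, counts are given over all genes tested and adjusted over the list alone. The NADPH oxidase list had 4 tested members and the immune and endothelial marker list 3, and neither was tested as a list. OAS1, KIF23 and RPL6 were not matched by symbol and are not analysed here. Histone genes carry the older symbols of the deposited table.

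Genes were named by a rule. IFI6 came first. Each comparison then gave the 12 largest rises and 12 largest falls among genes past the threshold whose libraries did not overlap the controls, or the 5 genes of smallest p where none passed. Each list that passed gave up to 4 members of smallest p. DDIT3, ATF3, ATF4, NOX4, HSPA5, IFIT1, ISG15, MX1, CDKN1A, MKI67 and HMOX1 were given whatever their values, and for lncRNA transcripts the 5 largest passing changes per direction. A few genes that the rule names are not reported here.

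Alternatives tried were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, limma without the trend or with a robust prior, fits of only the libraries compared, the replicate number as a block, an added threshold of 1 on the absolute log2 fold change, the deposited table of all annotated genes, and leaving out each library in turn. A correction for GC content and transcript length (lowess, span 0.3) and OE_IFI6 against sh_control were added after the data were seen. On data simulated from the real genes (10925 genes, 3 libraries per group), the overexpression contrast recovered 74% of genes changed by log2 1 and 38% of those changed by log2 0.58. The knockdown contrast recovered 74% and 36%. Of the calls in that simulation, 7.1% (9 calls) with overexpression and 4.1% (5 calls) with knockdown were of genes made with no change. The changed genes were drawn only from genes of higher level, so these rates do not cover genes nearest the 1 FPKM filter. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.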

Results

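RNA levels were compared in TE-1 cells, a human oesophageal cancer line, cultured for 48 h after transfection of vectors that raise or lower IFI6, an interferon-induced gene. The design asks which genes and pathways follow the level of IFI6. There were 3 libraries in each of 4 groups: OE_IFI6, its control OE_control, sh_IFI6 and its control sh_control. Summed FPKM over protein-coding genes was 325877 to 357145 per library, and 10650 to 10987 protein-coding genes reached 1 FPKM. Low values lay on steps that put the highest and the lowest library a factor of 1.29 apart in depth (29.8 to 38.4 steps per kilobase at 1 FPKM). The absolute depth is not given in the sources used here. The small RNAs RPPH1, RN7SK, RN7SL1, RN7SL2 and RMRP took 18.0% to 28.3% of all summed FPKM. Correlations of log2 values between libraries were 0.967 to 0.978 within groups and 0.954 to 0.978 between groups, and 0 pairs of libraries were identical. The 3 OE_control libraries stood apart from the other 9. On the first principal component, which held 23.1% of the variance, they lay at -30.6, -22.2 and -22.3, and the other 9 lay between 5.9 and 11.3.

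IFI6 (ENSG00000126709, chromosome 1, 27666064 to 27672198) followed the labels in its direction. Its level was 312 ± 45 FPKM (SD, n = 3) in OE_IFI6 against 24.7 ± 5.92 FPKM in OE_control, a ratio of 12.6. The log2 fold change was 3.62 (SE 0.17; limma adjusted p = 4.7e-07). In sh_IFI6 the level was 14.6 ± 0.646 FPKM (SD, n = 3) against 23.4 ± 1.97 FPKM in sh_control, which is 62.3% of the control level. The knockdown difference of -0.64 (SE 0.17) did not pass after adjustment over all genes (limma adjusted p = 0.82). For IFI6 alone, the target fixed in advance, the unadjusted limma p was 0.0024. The 3 libraries of each IFI6 group did not overlap those of its control, and the two-sided exact permutation p was 0.1 in both comparisons, the smallest this design allows. The control groups differed in IFI6 by log2 0.05 (limma adjusted p = 0.89). The transcript IFI6-202 (ENST00000361157) carried 97.5% of the gene's FPKM in OE_IFI6, 85.5% in OE_control, 90.0% in sh_control and 91.8% in sh_IFI6.

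**Figure D1:**
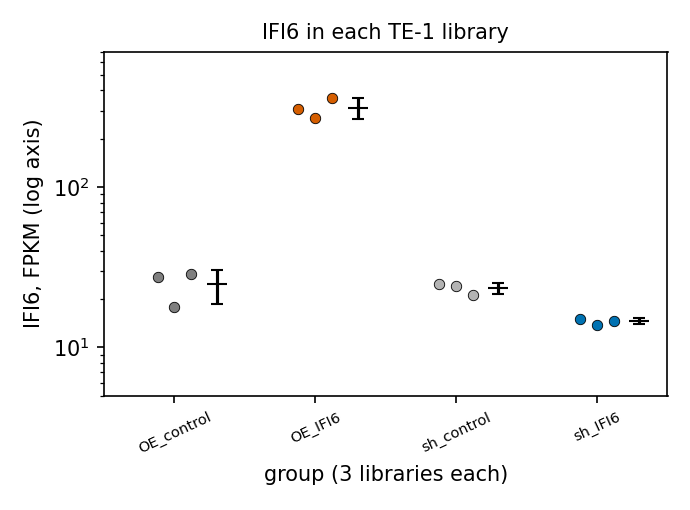
IFI6 level per library in FPKM on a log axis, for the 4 groups. Points are libraries and black bars are the mean ± SD of 3 libraries; the OE_IFI6 libraries lie between 268 and 358 FPKM and those of sh_IFI6 average 14.6 FPKM.

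Overexpression was accompanied by lower levels of heat shock and other stress genes relative to OE_control. In the heat shock list, 12 of 19 tested members fell and 0 rose (14 fell adjusted over the list alone), with a median log2 fold change of -0.90 (camera adjusted p = 5.51e-16; adjusted p = 0.0212 with an estimated correlation). HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946), an inducible HSP70 chaperone, fell from 134 ± 49.2 to 7.75 ± 1.79 FPKM, a log2 fold change of -3.90 (SE 0.26; adjusted p = 9.6e-06). HSPA1B fell by 3.60 on the log2 scale, and the split of reads between these near-identical copies is uncertain. DNAJB1 (ENSG00000132002, chromosome 19, 14514769 to 14565978), an HSP40 co-chaperone, fell from 272 ± 26.3 to 31.5 ± 1.69 FPKM (log2 -3.07, SE 0.10, adjusted p = 1.3e-08). The small heat shock protein gene HSPB1 fell from 522.5 ± 52.9 to 176 ± 25.4 FPKM (log2 -1.57, adjusted p = 3.8e-05). Levels in sh_control were 12.1 ± 2.44 FPKM for HSPA1A, 31.55 ± 1.27 FPKM for DNAJB1 and 193 ± 19.9 FPKM for HSPB1. The list's median between OE_IFI6 and sh_control was -0.07, and 0 of its members passed in that comparison.

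Targets of ATF4, a transcription factor of the integrated stress response, were lower as well. Of 29 tested members 15 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.13e-14; adjusted p = 0.0212 with an estimated correlation). DDIT3, which encodes the stress transcription factor CHOP, fell from 19.4 ± 2.27 to 4.11 ± 0.719 FPKM (log2 -2.00, SE 0.14, adjusted p = 1.2e-05). GDF15, a stress-induced cytokine gene, fell from 16.6 ± 0.667 to 2.64 ± 0.915 FPKM (log2 -2.31, SE 0.20, adjusted p = 6e-05), and SESN2 fell by 1.17 on the log2 scale. The asparagine synthetase gene ASNS fell by 1.54 on that scale, with 66.8% of its FPKM assigned to other isoforms. ATF4 itself had a log2 fold change of -0.39 (adjusted p = 0.033), and its call ended without OE_control 1 or 3 or OE_IFI6 1 or 2 (adjusted p = 0.073, 0.092, 0.1 and 0.08) and with quantile normalization (log2 -0.27, adjusted p = 0.083). ATF3 was too variable for a call (24.4 ± 18.7 against 12.7 ± 7.85 FPKM, SE 0.62, adjusted p = 0.45). The list's median was -0.67 without OE_IFI6 3, and between OE_IFI6 and sh_control it was -0.09.

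Unfolded protein response genes of the endoplasmic reticulum had 7 of 28 tested members that fell and 0 that rose (8 fell adjusted over the list alone). Their median was -0.28 (camera adjusted p = 5.26e-08), and the call was lost at adjusted p = 0.0538 with an estimated correlation. The chaperone gene HSPA5 fell from 289 ± 96.5 to 82.5 ± 7.40 FPKM (log2 -1.74, SE 0.22, adjusted p = 0.00099). HERPUD1 fell by 1.44, CALR by 0.88 and MANF by 0.85 on the log2 scale. The list's median between OE_IFI6 and sh_control was -0.05.

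Type I interferon-stimulated genes other than IFI6 split, with 7 of 27 tested members that fell and 1, IFIT5, that rose (the same counts adjusted over the list alone). IFIT5 lies outside the rule for named genes and was chosen after its values were seen. The list's median was -0.15 (camera adjusted p = 0.00016; adjusted p = 0.0538 with an estimated correlation), and lay between -0.24 with quantile normalization and -0.04 with no filter. OASL fell from 9.08 ± 0.862 to 1.76 ± 0.121 FPKM (log2 -1.87, adjusted p = 1.6e-05), ISG15 from 41.0 ± 5.99 to 14.7 ± 2.18 FPKM (log2 -1.42, adjusted p = 9.9e-05), and IFI44 by 1.64 on the log2 scale. IFIT1 had a log2 fold change of -0.52 (adjusted p = 0.033), a call that ended without OE_control 1, 2 or 3 (adjusted p = 0.093, 0.074 and 0.052) and without OE_IFI6 1 or 3 (0.084 and 0.08). MX1 stayed at or under 0.0182 FPKM on average in every group and NOX4, an NADPH oxidase, at or under 0.0424, so neither was tested. The interferon list's median between OE_IFI6 and sh_control was -0.01.

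Antigen presentation and NF-kB lists were lower with few members called. Of 17 antigen presentation genes of MHC class I, 2 fell and 0 rose (3 fell adjusted over the list alone; median -0.33, camera adjusted p = 1.61e-05; adjusted p = 0.0752 with an estimated correlation). The members that fell were CALR, a chaperone of the endoplasmic reticulum that also serves the unfolded protein response, and HLA-E, whose call at -0.46 ended without OE_control 1 or 3 or OE_IFI6 1 or 2 (adjusted p = 0.07, 0.081, 0.09 and 0.083). Of 13 NF-kB targets and cytokines 2 fell, RELB (-0.75) and NFKB2 (-0.52), and 0 rose (5 fell adjusted over the list alone; median -0.23, camera adjusted p = 0.0078; adjusted p = 0.178 with an estimated correlation). The NF-kB median was -0.12 without OE_control 2 and -0.40 without OE_IFI6 2. That list's call ended at adjusted p = 0.072 with a minimum of 5 FPKM, and the NFKB2 call without OE_control 2 or 3 or OE_IFI6 2 (adjusted p = 0.053, 0.084 and 0.081). The medians between OE_IFI6 and sh_control were -0.03 and -0.09.

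Genes of cholesterol and fatty acid synthesis had 10 of 31 members that fell and 0 that rose (12 fell adjusted over the list alone), with a median of -0.31 (camera adjusted p = 8.69e-09; adjusted p = 0.0392 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, fell from 97.9 ± 13.4 to 35.2 ± 3.16 FPKM (log2 -1.44, SE 0.12, adjusted p = 5.3e-05). MSMO1 fell by 1.12 and MVD by 0.83 on the log2 scale. Without OE_control 2 the median was -0.20. The list was lower in OE_IFI6 than in sh_control too, with a median of -0.18 (camera adjusted p = 0.000754; adjusted p = 0.485 with an estimated correlation). Of 29 hypoxia and glycolysis genes 6 fell and 1 rose (7 and 2 adjusted over the list alone; median -0.27, camera adjusted p = 4.15e-06; adjusted p = 0.0407 with an estimated correlation). The glucose transporter gene SLC2A3 fell from 1032 ± 60.8 to 481 ± 34.6 FPKM (log2 -1.10, adjusted p = 7.8e-05) and ADM by 1.23 on the log2 scale. The hypoxia median between OE_IFI6 and sh_control was -0.07.

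Mitotic, autophagy and p53 lists were lower as well. Of 34 mitotic genes 4 fell and 0 rose (10 fell and 1 rose adjusted over the list alone; median -0.31, camera adjusted p = 1.44e-05; adjusted p = 0.0816 with an estimated correlation). CKS2 fell by 0.75 and UBE2C by 0.62 on the log2 scale, and the proliferation marker MKI67 differed by 0.35 (adjusted p = 0.19). Of 30 autophagy and lysosome genes 4 fell and 0 rose, among them LAMP1 (-0.69) and ATG9A (-0.53), and 5 fell adjusted over the list alone (median -0.27, camera adjusted p = 1.49e-05; adjusted p = 0.0816 with an estimated correlation). Of 23 p53 targets 5 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.11, camera adjusted p = 0.00489; adjusted p = 0.178 with an estimated correlation). PMAIP1, a pro-apoptotic BH3-only gene, fell by 1.55 and ZMAT3 rose by 0.89, and CDKN1A, the p53-induced inhibitor p21, differed by -0.44 (adjusted p = 0.39). Without OE_control 2 the median was -0.18 for autophagy and -0.04 for p53 targets. Medians between OE_IFI6 and sh_control were -0.03, -0.06 and -0.06 for these lists.

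Mesenchymal and migration genes went both ways, with 4 of 17 that fell and 1 that rose (7 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.0215; adjusted p = 0.221 with an estimated correlation). The integrin gene ITGA5 fell from 80.4 ± 7.12 to 36.3 ± 4.59 FPKM (log2 -1.13, SE 0.11, adjusted p = 0.00016). CCN2, a matricellular growth factor gene, rose from 1.74 ± 0.506 to 7.14 ± 1.57 FPKM (log2 1.57, adjusted p = 0.00029). This list's call ended at adjusted p = 0.061 without OE_control 3, and its median lay between -0.38 with a minimum of 5 FPKM and 0.03 without OE_IFI6 2. Of 20 NRF2 targets 1, HMOX1, fell and 0 rose (3 fell adjusted over the list alone; median -0.13, camera adjusted p = 0.0237; adjusted p = 0.0816 with an estimated correlation). HMOX1, the haem oxygenase gene, differed by -0.79 (adjusted p = 0.029), and its call ended without OE_control 2 or 3 or OE_IFI6 1 or 2 (adjusted p = 0.064, 0.092, 0.091 and 0.094). Of 19 antioxidant enzymes 3 fell, among them SELENOW (-1.12) and CAT (-0.58), and 0 rose (6 fell adjusted over the list alone; median -0.05, or 0.03 with quantile normalization; camera adjusted p = 0.0181; adjusted p = 0.223 with an estimated correlation). Of 30 proteasome subunits 3 fell, among them PSMB2 (-0.66), and 0 rose (the same adjusted over the list alone; median -0.09, camera adjusted p = 0.029; adjusted p = 0.2 with an estimated correlation). The calls of these last 3 lists ended with quantile normalization (adjusted p = 0.079, 0.14 and 0.27) and without OE_control 1 (0.06, 0.14 and 0.06). With a minimum of 5 FPKM the NRF2 and proteasome calls ended (0.064 and 0.064), and with no filter the antioxidant call (0.054). The NRF2 call also ended without OE_IFI6 2 or 3 (0.11 and 0.061), the antioxidant call without OE_IFI6 2 (0.07) and the proteasome call without OE_control 3 or OE_IFI6 3 (0.17 and 0.075). The antioxidant median was 0.00 without OE_control 1 and -0.11 without OE_control 2, and the proteasome median was -0.15 without OE_control 2, -0.05 without OE_control 3 and -0.04 without OE_IFI6 1. The medians between OE_IFI6 and sh_control were -0.10, -0.04, 0.06 and 0.04 in the order given.

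Histone, ribosome biogenesis and epithelial junction genes were the lists that were higher in OE_IFI6. Of 20 replication-dependent histones 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.00361; adjusted p = 0.323 with an estimated correlation). HIST2H2BE rose by 0.80 and HIST1H1B by 0.85 on the log2 scale, and the list's call ended without OE_control 2 (median 0.23, adjusted p = 0.12). Of 30 MYC and nucleolar ribosome biogenesis genes 6 rose and 0 fell (10 rose adjusted over the list alone; median 0.25, camera adjusted p = 0.00379; adjusted p = 0.126 with an estimated correlation). NIP7 differed by 0.84 (adjusted p = 0.02) and ODC1 by 0.63 (adjusted p = 0.021). The NIP7 call ended without OE_control 2 or 3 or OE_IFI6 2 (adjusted p = 0.055, 0.063 and 0.072), and the ODC1 call without OE_control 2 or OE_IFI6 1 (0.062 and 0.065) and with quantile normalization (0.058). Of 12 epithelial junction genes 3 rose and 0 fell (the same adjusted over the list alone; median 0.21, camera adjusted p = 0.0215; adjusted p = 0.2 with an estimated correlation). The tight junction gene TJP1 rose by 0.93 and the desmosome gene DSP by 0.65. That list's call ended with no filter (median 0.01, adjusted p = 0.39) and without OE_control 1 (adjusted p = 0.11). Medians between OE_IFI6 and sh_control were 0.16 for histones (camera adjusted p = 0.000181; adjusted p = 0.755 with an estimated correlation), 0.00 for ribosome biogenesis and 0.01 for junction genes.

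Mitochondrial and squamous lists did not pass. Of 58 nuclear-encoded respiratory chain genes 0 passed, and of 9 mitochondrially encoded ones 0 passed (camera adjusted p = 0.558 and 0.974). Mitochondrial calcium transport had 2 of 14 that rose (0.802) and the mitochondrial unfolded protein response 1 of 24 each way (0.821). G1/S genes had 6 of 33 that rose and 1 that fell (0.142), and apoptosis regulators 3 of 28 that fell (0.16). Ferroptosis genes had 1 of 16 that rose and 2 that fell (0.198), and immediate early genes 6 of 27 each way (0.31). Squamous differentiation had 1 of 6 that fell (0.509), basal squamous identity 1 of 11 that fell (0.552), ribosomal proteins 2 of 47 that rose (0.867) and fibroblast markers 0 of 10 (0.56). Of 4 tested NADPH oxidase genes and 3 tested immune and endothelial markers 0 passed by limma, and these lists were too short to be tested. Direction differed between the median, the mean and the test for the nuclear-encoded respiratory chain and for squamous differentiation.

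Outside the stress groups, the largest rises after IFI6 were of DPH2 (log2 1.62), CCN2, RBMXL1 (1.54), LY6K (1.47), GAS1 (1.44), TRIM32 (1.43), MAPKAPK2 (1.36), C9orf116 (1.33), MYLK3 (1.31), FZD6 (1.31) and RPL34 (1.29). GAS1, a growth arrest gene, rose from 6.98 ± 0.208 to 20.7 ± 1.31 FPKM (adjusted p = 9.6e-06), and MAPKAPK2, a kinase downstream of p38, rose from 17.7 ± 1.03 to 46.9 ± 4.97 FPKM (adjusted p = 1.6e-05). RBMXL1 is a retrocopy of RBMX, and the split of reads between them is uncertain. RBMXL1 and TRIM32 each had 71.7% of their FPKM assigned to other isoforms between the groups, and the TRIM32 call ended without OE_control 1 or 2 or OE_IFI6 1 (adjusted p = 0.059, 0.051 and 0.059). Falls included the phosphatase gene DUSP5 (-1.88) and MICB (-1.59), a ligand of the NKG2D receptor. In sh_control GAS1 was at 22.2 ± 1.19, MAPKAPK2 at 51.2 ± 1.29 and DUSP5 at 30.0 ± 1.5 FPKM, near OE_IFI6.

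**Figure D2:**
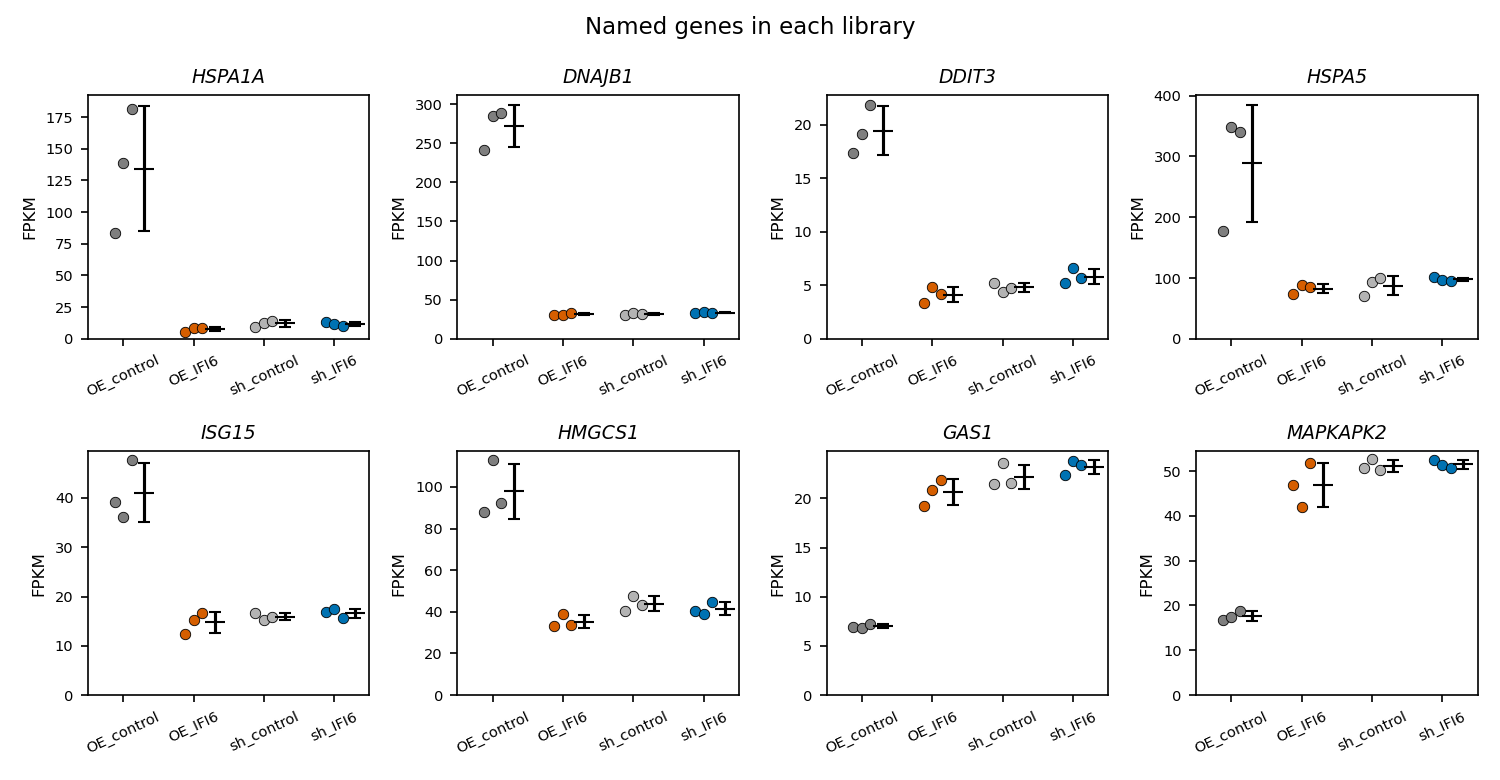
Levels in FPKM of HSPA1A, DNAJB1, DDIT3, HSPA5, ISG15, HMGCS1, GAS1 and MAPKAPK2 in the 4 groups. Points are libraries and black bars are the mean ± SD of 3; OE_control stands apart from the other 3 groups for each gene, as with DNAJB1 at 272 FPKM against 31.5 to 33.2.

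In all, 837 of 10925 genes passed for OE_IFI6 against OE_control (limma), of which 448 rose, 389 fell and 98 changed by at least log2 1. The share that rose was 53.5% as deposited, 45.2% of 944 after median-of-ratios scaling, 43.9% of 846 after quantile normalization and 46.5% of 1416 after the GC and length correction, so the direction of the majority depended on scaling. Unadjusted p was under 0.05 for 2562 genes (23.5%, against 5% by chance), and the groups did not overlap for 2544 (23.3%, against 10% by chance). Of the 30 lists tested 18 passed, 15 lower and 3 higher; with quantile normalization 17 passed, 12 lower and 5 higher. Heat shock, ATF4 targets, cholesterol synthesis and hypoxia and glycolysis, 4 lists, held with an estimated correlation. Fitting only the 6 libraries compared gave 167 genes, and ended 33 calls of genes picked by the rule at adjusted p between 0.054 and 0.25. Among those named here these were ATF4, IFIT1, HLA-E, RELB, NFKB2, HMOX1, CAT, UBE2C, ZMAT3, HIST1H1B, NIP7, ODC1, DSP, PSMB2, ATG9A and LAMP1. Leaving out OE_control 3 or OE_IFI6 2 gave 503 and 526.

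**Figure D3:**
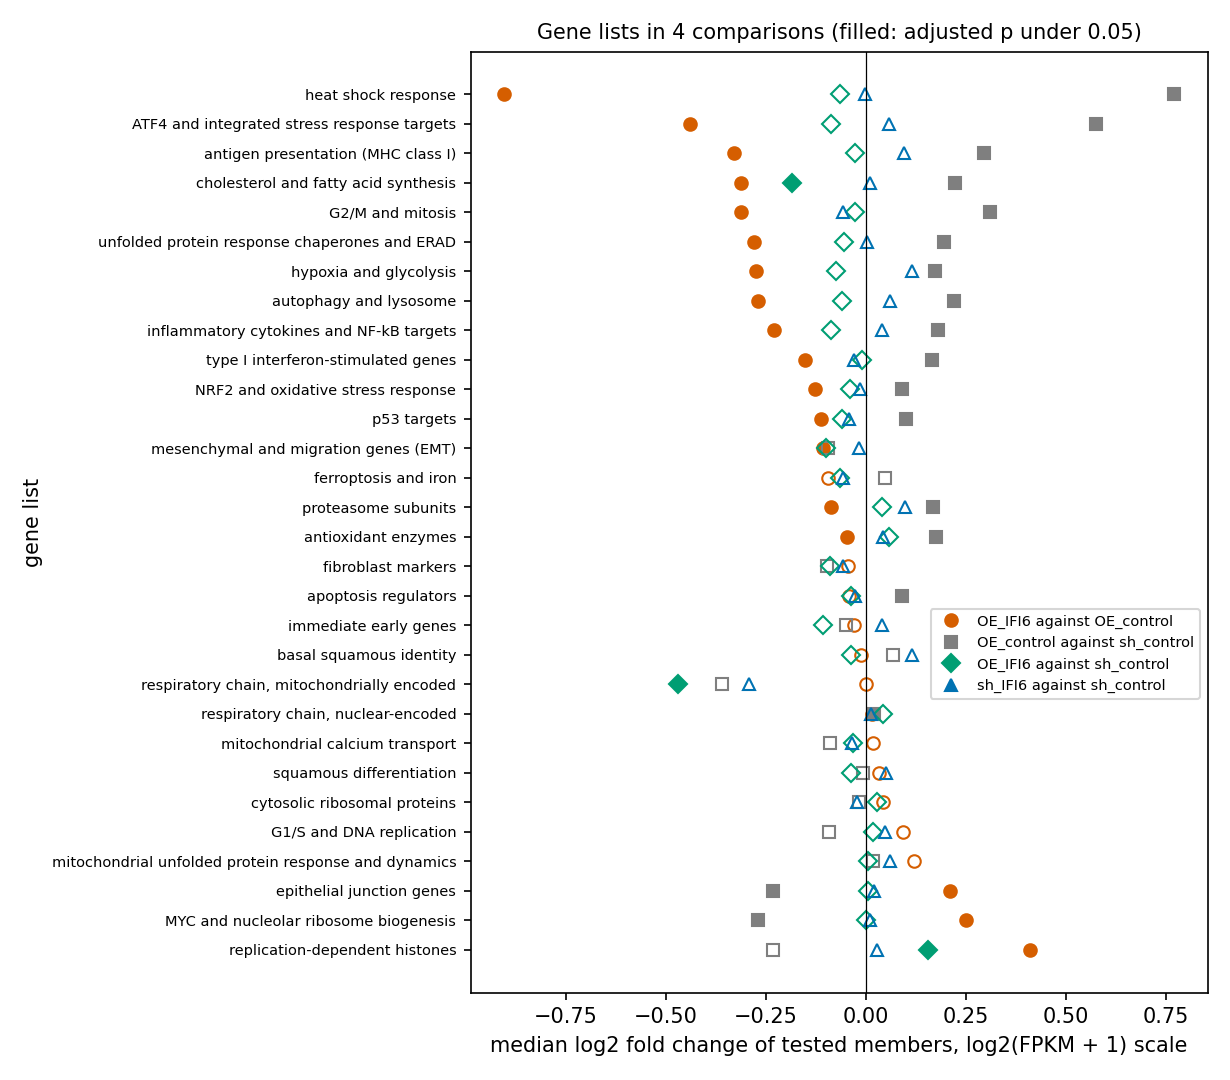
Median log2 fold change of the tested members of each gene list in 4 comparisons, on the log2(FPKM + 1) scale. Filled points mark adjusted p under 0.05 by camera with the preset correlation; the heat shock list lies at -0.90 for OE_IFI6 against OE_control and at -0.07 for OE_IFI6 against sh_control.

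The control groups themselves differed in heat shock and ATF4 target genes. Whether the overexpression and hairpin groups were cultured or sequenced together is not given in the sources used here, so vector and batch cannot be told apart in this comparison. Heat shock genes were higher in OE_control than in sh_control, with 11 of 19 members up and 0 down (15 up adjusted over the list alone; median 0.77, camera adjusted p = 5.73e-17; adjusted p = 0.0176 with an estimated correlation). ATF4 targets were higher with a median of 0.58, 16 of 29 up and 2 down (17 and 3 adjusted over the list alone; camera adjusted p = 4.35e-14; adjusted p = 0.0176 with an estimated correlation). In all 822 genes differed (limma), 300 higher and 522 lower in OE_control (36.5% higher). That split depended on scaling, with 838 genes and 57.3% higher after median-of-ratios scaling and 708 genes and 53.4% higher after quantile normalization. Of the 30 lists 18 passed, 16 higher and 2 lower in OE_control, and 2 held with an estimated correlation. Leaving out OE_control 1 or 3 gave 512 and 543 genes, and leaving out sh_control 1, 2 or 3 gave 440, 319 and 405; 429 passed when only these 6 libraries were fitted.

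Compared with sh_control, OE_IFI6 had 2 genes that passed (limma), IFI6 (log2 3.67) and RBMXL1 (1.49). This comparison was chosen after the data were seen. Unadjusted p was under 0.05 for 503 of 10925 genes. With the OE_control libraries left out of the fit the count was also 2, with 574 at unadjusted p under 0.05 (IFI6 adjusted p = 1.1e-06, RBMXL1 adjusted p = 0.0049). The 837 genes called for OE_IFI6 against OE_control had a median absolute log2 difference of 0.0959 between OE_IFI6 and sh_control, and the uncalled genes of 0.107. Of the lists, 3 passed in the model of 12 libraries (histones higher, cholesterol synthesis lower, mitochondrially encoded respiratory chain lower at a median of -0.47) and 0 held with an estimated correlation. The mitochondrially encoded list rests in part on low values, since 9 of its 13 members reached the filter. Genes lower in OE_IFI6 than in OE_control and also higher in OE_control than in sh_control numbered 241, and 335 showed the converse. Unchanged groups simulated against the shared OE_control libraries gave 0 and 0, which was nearly fixed because such groups give few calls, and independent lists of these sizes would share 10.7 and 21.4. The fold changes of these comparisons had a correlation across genes of -0.79 (simulated -0.50) and a covariance of -0.094 (simulated -0.025). Part of the excess over independent lists may come from the shared controls, since 3 libraries cannot be split.

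Knockdown of IFI6 was accompanied by no gene past the threshold. Of 10925 genes 0 passed (limma), 563 had unadjusted p under 0.05 (5.2%, against 5% by chance), and the groups did not overlap for 2084 (19.1%, against 10% by chance). The genes of smallest p, none of which passed, were SPIN2B (log2 0.88, adjusted p = 0.27), AHR (-0.91, adjusted p = 0.27), DDX54 (0.73, adjusted p = 0.37), SMIM29 (-0.82, adjusted p = 0.37) and MPHOSPH8 (-0.97, adjusted p = 0.56). AHR, a ligand-activated transcription factor, was at 11.9 ± 0.630 FPKM in sh_IFI6 against 23.3 ± 1.98 FPKM in sh_control. A gene's value sums its transcripts, and most of this difference lay in AHR-205, tested with the lncRNA transcripts. AHR-205 was at 0.178 ± 0.05 FPKM in sh_IFI6 against 11.2 ± 1.05 FPKM in sh_control. It also belonged to the transcripts nearly absent from all libraries of a group, described below. Stress and interferon genes fixed in advance did not pass: ATF3 differed from sh_control by 0.42 (SE 0.62; 0.19 to 0.82 under the alternatives), ATF4 by 0.10 (SE 0.10), DDIT3 by 0.23 (SE 0.14), HSPA5 by 0.17 (SE 0.22), ISG15 by 0.06 (SE 0.13), IFIT1 by -0.01 (SE 0.13) and HMOX1 by 0.04 (SE 0.19). Of the 30 lists 0 passed with the preset or the estimated correlation or with fry, and 4 had unadjusted camera p under 0.05 (hypoxia, proteasome and MHC class I higher, mitochondrially encoded respiratory chain lower; lowest adjusted p = 0.292). Single genes passed under other settings. YIPF6 passed at 1.29 in a fit of only these libraries (adjusted p = 0.05), PHLDA3 at 1.33 without sh_IFI6 1 (adjusted p = 0.016) and KLF10 at -1.32 without sh_IFI6 2 (adjusted p = 0.032), each at adjusted p = 0.82 in the model of 12 libraries, and these 3 were chosen after their values were seen.

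The effects of overexpression and knockdown differed for 294 genes in the test of the difference itself (limma), 129 more positive and 165 more negative with overexpression. DNAJB1 had the difference of -3.14 (SE 0.14, adjusted p = 5.3e-07) and HSPA1A of -3.87 (SE 0.37, adjusted p = 0.00031). Of the lists 14 passed, 13 more negative and 1 more positive with overexpression, and ATF4 targets, heat shock and hypoxia, 3 lists, held with an estimated correlation. The count moved by over 1.5 times without OE_control 3 (158 genes), OE_IFI6 1, 2 or 3 (183, 181 and 518), sh_control 1, 2 or 3 (123, 142 and 152) or sh_IFI6 1, 2 or 3 (174, 123 and 125). Across genes, which are not replicates, the fold changes had a Pearson correlation of -0.09 and a Spearman correlation of -0.12. Genes called in opposite directions numbered 0 (Fisher's exact test p = 1), since knockdown gave 0 calls. Of the 837 genes called with overexpression, 488 (58.3%) had the opposite sign with knockdown, against 53.6% of the uncalled genes.

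Among transcripts in the lncRNA table, HMG20B-212 (ENST00000487894, chromosome 19, 3575651 to 3578671), a retained-intron transcript, was at 59.4 ± 10.7 FPKM in OE_control and 0.428 ± 0.180 FPKM in OE_IFI6 (log2 -5.39, adjusted p = 6.3e-07). With knockdown it rose from 0.499 ± 0.197 to 56.1 ± 1.44 FPKM (log2 5.26, adjusted p = 8.1e-07), while the total of HMG20B differed by -0.65 (adjusted p = 0.11) and 0.39 (adjusted p = 0.82). HMG20B-212 thus differed about as much between OE_control and sh_control, though these control groups differed in IFI6 by only log2 0.05. Of 6496 transcripts 16 passed with overexpression, 7 higher and 9 lower (8 and 6 of 14 with median-of-ratios scaling and likewise with quantile normalization), and 735 had unadjusted p under 0.05. The 5 largest rises were OXA1L-207 (2.65), RBMX-205 (2.21), MBTPS1-204 (2.14), the lincRNA AC245014.3-201 (1.79) and SNHG8-206 (1.36). The next largest falls were HMGCS1-205 (-2.09), HMGCS1-203 (-1.60), HMGCS1-207 (-1.53) and GABRE-207 (-1.49). In sh_control RBMX-205 (19.1 FPKM), AC245014.3-201 (34.9) and SNHG8-206 (7.14) lay near OE_IFI6 (17.7, 40.9 and 8.36). OXA1L-207 and MBTPS1-204 did not, at 2.785 and 0.879 FPKM in sh_control against 36.1 ± 18.1 and 9.95 ± 0.299 in OE_IFI6. These falls stood at 2.6, 4.903, 7.394 and 1.976 FPKM in sh_control, in the order given, and at 1.701, 3.245, 4.432 and 1.78 in OE_IFI6. OE_IFI6 was not tested against sh_control for transcripts. With knockdown 3 transcripts passed, and 367 had unadjusted p under 0.05. AHR-205 fell from 11.2 ± 1.05 to 0.178 ± 0.05 FPKM (log2 -3.37, adjusted p = 4.4e-05) and HS6ST1-203 fell by 2.21 on the log2 scale (adjusted p = 0.032). Of these calls, 12 of 16 and 3 of 3 were transcripts of genes in the protein-coding table, as were 5698 of the 6496 transcripts tested. The count with overexpression was 7 with no filter, 38 with a minimum of 5 FPKM and 6 with only the libraries compared, and that with knockdown was 10 with no filter and 10 with only the libraries compared. The count with overexpression moved to 3, 8, 8 and 7 without OE_control 1, OE_control 2, OE_IFI6 1 or OE_IFI6 2, and that with knockdown to 6, 6 and 8 without sh_control 1, 2 or 3.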

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

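Several tests of the stress gene pattern were chosen only after the result was seen. They were those of scaling, of GC content and length, of another state of the OE_control cultures and of the level of IFI6. The other tests in this part were chosen before, though the lists and members of the stress gene pattern were picked from its results.

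The change from OE_control to OE_IFI6 differed from the change from sh_control to sh_IFI6 for the genes given here, by the test of the difference itself. The difference (overexpression effect minus knockdown effect, log2) was -3.87 for HSPA1A, -3.56 for HSPA1B, -3.14 for DNAJB1, -1.68 for HSPB1, -1.91 for HSPA5, -2.23 for DDIT3 and -2.46 for GDF15. It was -2.13 for OASL, -1.58 for IFI44, -1.87 for MICB and -1.97 for DUSP5. Genes with a positive difference were IFI6 itself (4.27), CCN2 (1.77), RBMXL1 (1.67), MYLK3 (1.54), DPH2 (1.53), LY6K (1.47), GAS1 (1.38), MAPKAPK2 (1.35), RPL34 (1.35), C9orf116 (1.31) and FZD6 (1.23). Each of these genes passed at limma adjusted p under 0.05. Those other than IFI6 were picked for the largest changes between OE_IFI6 and OE_control, and the test of the difference uses the same libraries. That they passed is therefore no separate evidence.

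Gene lists that passed camera for the difference had medians of -0.91 for heat shock, -0.64 for ATF4 targets, -0.50 for MHC class I, -0.42 for hypoxia and glycolysis, -0.29 for cholesterol synthesis and -0.28 for autophagy. Smaller medians were -0.27 for NF-kB targets, -0.26 for the unfolded protein response, -0.22 for mitosis, -0.16 for interferon-stimulated genes, -0.16 for the proteasome, -0.14 for p53 targets and -0.12 for antioxidant enzymes. Histones had a median of 0.38. With an estimated correlation, heat shock (adjusted p = 0.0368), ATF4 targets (0.0363) and hypoxia (0.0392) held. The other calls were lost, at adjusted p = 0.108 for MHC class I, 0.0947 for cholesterol synthesis, 0.112 for autophagy, 0.275 for NF-kB targets, 0.139 for the unfolded protein response and 0.272 for mitosis with an estimated correlation. For interferon-stimulated genes it was 0.108, for the proteasome 0.168, for p53 targets 0.282, for antioxidant enzymes 0.298 and for histones 0.503. The gene count was 294, and the highest of 99 other regroupings within the 2 comparisons was 198, so 1 of 100 regroupings, the real one, gave as many. That share was under 0.05 for both comparisons regrouped together. Chance is not excluded for the overexpression libraries alone or for the knockdown libraries alone. Only 11 regroupings kept the overexpression groups whole, too few for a share under 0.05, and these reached 198. Where the groups were broken up, the highest was 2, so the count rested on the overexpression split. The share of 1 of 100 therefore does not exclude chance for a difference between the effects.

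The heat shock, ATF4, unfolded protein and interferon lists held 41 members, of 103, that were lower in OE_IFI6 than in OE_control, at a median log2 of -0.93. Scaling, GC content with transcript length, and a single OE_control library are argued against as the whole cause: 41 members were still called after median-of-ratios scaling, 41 after the GC and length correction, and at least 31 with any OE_control library left out. A state of the OE_control cultures unrelated to IFI6 remains a candidate explanation, because these members differed by a median of -0.016 between OE_IFI6 and sh_control (-0.093 to 0.045 with a library left out), where IFI6 differed by 3.67. That IFI6 lowers a stress state brought on by the control vector's transfection would give the same values, so the design does not separate the alternatives. Whether the level of IFI6 lowers these genes whatever the vector cannot be told apart from no effect: the knockdown median was 0.072 (0.04 to 0.091 with a library left out), and the knockdown left 62.3% of IFI6.

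For the comparisons of 3 libraries against 3, the 10 splits of the 6 libraries are too few for a share under 0.05. The genes changed with overexpression numbered 837 in the real split against 1 in the highest other, the lncRNA transcripts 16 against 2 and the gene lists 18 against 10. With knockdown the values were 0 against 2 for genes, 3 against 5 for lncRNA transcripts and 0 against 4 for gene lists. The control groups gave 822 against 4.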

How the results depend on the processing

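The GC content and length correction and the comparison of OE_IFI6 with sh_control were the tests chosen only after the result was seen; the rest were chosen before. No called gene and no list test reversed direction; the antioxidant median turned to 0.03 with quantile normalization and the mesenchymal median to 0.03 without OE_IFI6 2. Of the main values, 177 of those under alternatives stayed within 1.5 times or on the same side, and 43 moved. Among values of single genes and lists, 1729 stayed on their side, 148 lost the call and 11 gained it; 34 of 103 gene calls ended under at least 1 alternative, as did 7 of 18 list calls apart from the estimated correlation, which left 4. Robust eBayes was not run for the lists, since camera takes no such prior.

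Genes changed with overexpression (837) numbered 167 when only the 6 libraries were fitted, where fewer residual degrees of freedom remain, 98 with an added fold threshold, 1416 after the GC and length correction, and 2 against sh_control with the OE_control libraries left out. Of the 837, 795 were also called after median-of-ratios scaling, 711 after quantile normalization and 802 after the GC and length correction. For OE_control against sh_control (822) the counts were 429, 98 and 1305 under the first 3 of these settings, and for the difference of effects (294) 127 with the fold threshold. Genes changed with knockdown (0) numbered 1 in a fit of only its libraries. Lists changed with overexpression (18) numbered 4 with an estimated correlation and 4 against sh_control with the OE_control libraries left out (3 with them in the model). Among lncRNA transcripts, overexpression calls (16) numbered 7 with no filter, 38 with a minimum of 5 FPKM and 6 with only the libraries compared; knockdown calls (3) numbered 10 with no filter and 10 with only the libraries compared. Beyond the number of features or libraries, the cause was not tested.

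Leaving out each library in turn gave 503 to 859 genes with overexpression, 0 to 1 with knockdown, 123 to 518 for the difference of effects and 319 to 769 between the controls. lncRNA transcripts numbered 3 to 17 and 2 to 8, and lists 15 to 19 and 0 to 0. The IFI6 log2 fold change was 3.42 to 3.75 with overexpression and -0.71 to -0.60 with knockdown. The correlation of effects across genes was -0.184 to -0.023, and opposite calls stayed at 0.

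Whether replicate numbers pair the samples stays open for the overexpression groups, and the knockdown groups showed no pairing. Deviations of same-numbered libraries correlated at 0.09, 0.25 and 0.12 in the overexpression groups, each best with its own number, and at -0.04, -0.01 and -0.03 in the knockdown groups. With the number as a block, 5 lncRNA transcripts passed with overexpression and 2 with knockdown, and genes numbered 802 with overexpression, 250 for the difference of effects and 776 between the controls. Depth limits values near 1 FPKM, and is known only relative to other libraries.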

Other observations

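The tests of RBMXL1 were chosen only after the result was seen; the test of transcripts nearly absent from a group was chosen before.

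Immediate early genes, which respond within minutes to growth factors and stress, went both ways between OE_IFI6 and OE_control. FOS (log2 0.68), JUN (0.65), JUNB (0.58), EGR1 (0.94), DUSP2 (0.77) and KLF2 (0.84) rose, and DUSP1 (-0.71), DUSP5 (-1.88), IER3 (-1.01), IER5 (-0.50), KLF4 (-0.42) and KLF6 (-0.56) fell, all 12 at limma adjusted p under 0.05. The basal keratin gene KRT17 fell by 1.44 on the log2 scale (limma adjusted p = 0.0012) and ANXA1, an annexin gene of the squamous differentiation list, by 0.88 (limma adjusted p = 0.0064). The mitophagy receptor gene BNIP3L rose by 1.07 (limma adjusted p = 0.00072). FOS and EGR1 in OE_IFI6 differed from sh_control by -0.17 and 0.00. These genes except DUSP5 lie outside the rule and were chosen after their values were seen.

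MT-CO1 stood at 675.1 to 1197.6 FPKM per library, while the median of the other 12 mitochondrial protein genes was 2.22 to 3.64 FPKM. Results for the mitochondrially encoded respiratory chain list therefore rest in part on values near the 1 FPKM filter.

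HMG20B-212, near 0 in OE_IFI6 and sh_control and above 50 FPKM in the other groups, belonged to a wider pattern of transcripts present in all libraries of a group at 5 FPKM or more and at least 10 times lower in all libraries of the other. There were 34 between OE_IFI6 and OE_control (other splits of those libraries 15 to 30, median 23) and 25 between sh_IFI6 and sh_control (other splits 16 to 40, median 21). Other splits reached 40 such transcripts in the knockdown libraries and 30 in the overexpression libraries. Unstable assignment of reads between isoforms is therefore a candidate explanation for many of them. The 34 of the overexpression comparison exceeded every other split of its libraries and include IFI6-202, the main transcript of the overexpressed gene. HMG20B-212 did not follow the level of IFI6 across the control groups. It was at 59.4 FPKM in OE_control and 0.499 FPKM in sh_control, where IFI6 was at 24.7 and 23.4 FPKM. These values argue against the level of IFI6 as the whole cause for this transcript, and no other biological explanation was tested.

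RBMXL1 (chromosome 1, 88979456 to 88992960), a retrocopy of RBMX, was higher in OE_IFI6 than in the other groups, at 7.67 ± 1.5 FPKM against 1.97 ± 0.301, 2.06 ± 0.0905 and 1.80 ± 0.140 FPKM in OE_control, sh_control and sh_IFI6. Most of it was assigned to RBMXL1-204, at 5.72 ± 2.29 FPKM. Assignment among isoforms of RBMXL1 alone is argued against, since the lowest OE_IFI6 library's summed RBMXL1 value was 3.21 times the sh_control mean. Reads shared with the parent gene RBMX stay open: RBMX differed by -0.09 (SE 0.16) on the log2 scale between OE_IFI6 and sh_control, where a move of the gained 5.61 FPKM from RBMX would give -0.19, and it rose by 0.74 against OE_control (limma adjusted p = 0.016). That RBMXL1 follows the overexpression of IFI6 is a hypothesis that stays open, and carry-over of vector sequence was not tested.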
